A study of Mus musculus with 6 samples.

How the data were processed

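CD45+ blood cells of 3 streptozotocin-diabetic mice were profiled by droplet single-cell RNA sequencing (Chromium Single Cell 3' v3), with 2 libraries per mouse. Per the labels, each mouse gave 1 library marked T1 and called diabetic. The T2 library of mouse 2416 is called delayed gastric emptying, and the T2 libraries of mice 2860 and 2863 are called normal gastric emptying. The meaning of T1 and T2 is not given in the sources used here. Per the submitters' processing notes, the deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode. The authors made them with Cell Ranger version 4.0 on mm10, in the tables of barcodes called as cells; the annotation release is not given in the sources used here. All values are whole numbers over 32285 genes. Mass cytometry, which the study's description names, was not analysed here.

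In the order diabetic 2416, delayed 2416, diabetic 2860, normal 2860, diabetic 2863 and normal 2863, the libraries held 32109794, 47862623, 29437474, 22886799, 31309845 and 34144920 UMIs, over 3280 to 5523 barcodes. Barcodes were kept with at least 200 detected genes and at most 10% mitochondrial UMIs, which left 21716. The barcodes removed for too few genes numbered 348, 247, 133, 966, 213 and 509 in the same order. Doublets were scored per library with Scrublet as run by scanpy 1.11.5. The 418 cells (1.93%) with a score above 0.25 were removed after the clusters had been made and named, leaving 21298.

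For naming cells, UMIs were scaled to 10000 per cell and log-transformed. All kept cells, doublets included, were clustered. The 2000 most variable genes gave 30 principal components, a graph of 15 neighbours and 35 Leiden clusters at resolution 1 (leidenalg 0.10.2, python-igraph 0.11.9). Receptor V, D and J segments, mitochondrial, haemoglobin and ribosomal protein genes, symbols of the form Gm with a number, and Xist were left out of that choice of genes. No batch correction was applied. Each cluster was scored on 14 marker lists, as the mean log2 ratio of its marker CPM to that of the median cluster, with 5 CPM added to each. A name needed a score of at least 3, a margin of 1.5 over the next class, at least 3 markers seen in more than 10% of its cells and doublets in less than 40%. A name was also withheld where the 10 leading genes held more markers of another class, or where the median UMI count lay under a 0.333 fraction of the library's median without own markers leading. These thresholds and the doublet score were chosen after the clusters had been seen. They left 12 clusters unnamed, holding 4.48% and 4.45% of the cells of mouse 2416 (T1 and T2), 6.47% and 10.4% of mouse 2860, and 5.68% and 9.32% of mouse 2863. Ly6c2, Vcan and Chil3 were among the markers that name classical monocyte-like cells, and S100a8, Retnlg and Mmp8 were among those that name neutrophil-like cells.

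UMIs were summed per library over the cells of a class. Classical monocyte-like sums ran from 2014477 to 8066789 UMIs. Genes with at least 10 UMIs in at least 2 libraries were tested: 10653 in classical monocyte-like, 9072 in neutrophil-like, 12435 in B cell-like and 11796 in T cell-like cells. Counts were modelled with edgeR 4.0.16 (TMM factors, glmQLFit and glmQLFTest, log CPM with a prior count of 2) on R 4.3.3. The 4 comparisons were T2 against T1 (3 and 3 libraries, 4 residual degrees of freedom) and, in a fit of all 3 groups (3 residual degrees of freedom), normal emptying against diabetic, delayed emptying against diabetic, and delayed against normal emptying. The delayed group has 1 library, so its spread is assumed equal to that of the other groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. These comparisons, the marker and gene lists, the naming rule for genes and the alternatives were fixed before the data were examined.

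The same mouse gave a T1 and a T2 library, so mouse was fitted as a block beside every comparison, with 2 residual degrees of freedom for T2 against T1 and 1 for the groups. For delayed against normal emptying the block compares the T2 minus T1 change of mouse 2416 with the mean change of the other mice. As a check of the pairing, log CPM centred within T1 and within T2 was correlated across genes, which are not independent replicates. In classical monocyte-like cells the same mouse gave -0.0127, -0.0687 and -0.0357 for mice 2416, 2860 and 2863. Neutrophil-like cells gave 0.0182, 0.0487 and -0.0107, B cell-like cells 0.0605, 0.043 and 0.0482, and T cell-like cells 0.0716, 0.157 and 0.0038. Libraries of different mice gave -0.0409 to 0.0735, -0.0768 to 0.0522, -0.0374 to -0.0066 and -0.145 to 0.0831 in the same order of classes. The same mouse stood above different mice throughout in B cell-like cells alone. In classical monocyte-like cells the check does not show the pairing, which rests on the labels.

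Gene lists (26, at least 5 tested members each; 25 reached that in classical monocyte-like cells) were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. Beside it, camera was run with an estimated correlation, and fry for the movement of a list on balance. Counts of list members are given over all genes and adjusted over the list alone. No list call in any comparison of classical monocyte-like cells held with an estimated correlation. The first list adjustment is over 25 lists in each of 4 comparisons, 100 tests in that class.

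Genes named in the text follow a rule: the genes of the proteins in the series title (among them Ly6c2 and Ly6c1, Ly6g and Cx3cr1); then the 10 largest changes each way (5 in other classes) among called genes with a mean of at least 50 CPM and 1 sign throughout; then up to 4 members per list with the smallest p. Symbols of the form Gm with a number, symbols ending in Rik and receptor V and J segments were left out of the ranking, as were lists of transcripts of other cells. Where no gene passed, the 3 with the smallest p are named. A few genes that this rule takes are not reported here.

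Shares of cells carry exact Clopper-Pearson 95% intervals; these and the 3-count limits for zeros cover counting error only. The T2 minus T1 change of a share was tested with a two-sided exact sign-flip permutation over 3 mice, whose smallest p is 0.25. Shares over leukocytes alone, leaving out platelet-like and erythroid cell-like cells, were added after the data were seen. For the share of cells with a UMI, each cell was thinned to 2000 UMIs (or 1000) and cells with fewer were left out.

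Alternatives were DESeq2 1.42.0, its size factors within edgeR (RLE), no low-count filter, the mouse block, doublets kept, at least 500 genes with at most 5% mitochondrial UMIs, resolution 2 (49 clusters), and each library left out in turn. DESeq2 left 9088, 4544, 10120 and 3098 of the classical monocyte-like genes without an adjusted p in the 4 comparisons, 5, 6156, 3166 and 3342 of the neutrophil-like, 6509, 6268, 1206 and 965 of the B cell-like and 0 of the T cell-like genes, so its counts cover fewer genes. The tests were tested on simulated data with 200 of the genes changed. In classical monocyte-like cells 71.6%, 62.7%, 61.2% and 44.8% of 2-fold changes were recovered in the 4 comparisons in the order above, 34.3%, 22.4%, 16.4% and 5.97% of 1.5-fold changes and 95.5%, 93.9%, 95.5% and 80.3% of 4-fold changes. Unchanged genes called beside them numbered 11, 15, 17 and 10, which is 7.59%, 11.2%, 12.9% and 10.3% of the calls. For neutrophil-like cells the 2-fold recovery was 52.2%, 58.2%, 50.7% and 41.8%, for B cell-like cells 83.6%, 71.6%, 58.2% and 61.2%, and for T cell-like cells 76.1%, 80.6%, 56.7% and 62.7%. Unchanged genes called there numbered 8, 6, 23 and 9 in neutrophil-like, 13, 11, 7 and 11 in B cell-like and 11, 10, 12 and 15 in T cell-like cells, or 5.45% to 18.1% of the calls. The share of false calls was thus above the 5% that is set in each comparison and class. Of 100 random lists of 30 genes, 4 had a raw p under 0.05 and 0 were called. The genes were simulated independently, for T2 against T1 in classical monocyte-like cells alone. How the list test behaves for genes that move together is therefore not shown. All 10 splits of the 6 libraries into 3 and 3 were fitted for T2 against T1.

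Positions are from GENCODE M21 (GRCm38), in which 32235 of the 32285 gene identifiers were found (99.8%). Reads of near-identical genes may be shared or lost between copies, so values of Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Ly6c1 and Ly6c2, Rnaset2a and Rnaset2b, Iglc1 and Iglc2, Bcl2a1b and Bcl2a1d, the Slfn and Ifi families, and Rps27rt carry that uncertainty. Tsix overlaps Xist on the opposite strand. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used for the remaining steps.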

Results

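CD45+ blood cells of 3 diabetic mice were sequenced at T1 and at T2. The series concerns circulating monocyte subsets, told apart by surface proteins that include Ly6C, Ly6G and Cx3CR1, in diabetic mice with and without delayed gastric emptying. There were 3 diabetic T1 libraries (mice 2416, 2860 and 2863), 1 T2 library with delayed emptying (mouse 2416) and 2 T2 libraries with normal emptying (mice 2860 and 2863). In the order diabetic 2416, delayed 2416, diabetic 2860, normal 2860, diabetic 2863 and normal 2863, the libraries held 3773, 4947, 3016, 2584, 3082 and 3896 single cells. The median UMI counts of the cells kept were 6760, 8067, 7281, 5653, 7948.5 and 6282, over a median of 2397.5, 2246, 2372, 1983, 2597 and 2244 genes. Classical monocyte-like cells, the class the series is about, numbered 222, 382, 235, 175, 216 and 196.

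How did the make-up of blood differ between T1 and T2? T cell-like cells made up a smaller share at T2 in all 3 mice. It was 16.6% (95% interval 15.4 to 17.8) at T1 and 6.25% (5.59 to 6.96) at T2 in mouse 2416. The shares were 16.3% (15 to 17.6) and 9.02% (7.94 to 10.2) in mouse 2860, and 23.7% (22.2 to 25.2) and 17.8% (16.6 to 19.0) in mouse 2863. The mean change was -7.84 ± 2.28 points (SD, n = 3 mice; exact two-sided sign-flip permutation p = 0.25, the smallest that 3 mice can give). Finer clustering gave a mean of -6.86, with -3.48 in mouse 2860 in place of -7.26. An unnamed cluster with T and B cell markers, left out of the class, held 24 cells (0.796%) of diabetic 2860 and 109 (4.22%) of normal 2860. Dendritic cell-like and erythroid cell-like cells also moved one way in the 3 mice, up by 0.155, 0.454 and 0.602 points and by 0.504, 0.575 and 0.409 points in mice 2416, 2860 and 2863 (exact permutation p = 0.25 for each). Under that test any class without a change moves one way in 3 mice with a probability of 0.25. The p were not adjusted over the classes. Neutrophil-like cells went from 13.9% (12.8 to 15.1) to 30.4% (29.1 to 31.7) in mouse 2416, the mouse with delayed emptying. They changed by -0.448 and -5.17 points in the normal-emptying mice 2860 and 2863. Their mean change, 3.61 ± 11.4 points (SD, n = 3; exact permutation p = 1), was smaller than the spread between mice. The mean without the delayed library was -2.81. Platelet-like barcodes went from 0.928% to 15.7% in mouse 2416, from 6.33% to 3.25% in mouse 2860 and from 1.62% to 4.26% in mouse 2863. With the stricter cell filter the platelet-like change was 3.05 points in mouse 2416 in place of 14.8, and the mean change 0.348 in place of 4.79. With platelet-like and erythroid cell-like barcodes left out of the total, neutrophil-like cells still differed by 22.3 points in mouse 2416, and T cell-like cells by -7.61 ± 1.97 points (SD, n = 3).

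Classical monocyte-like cells took 5.88% (5.15 to 6.68) and 7.72% (6.99 to 8.50) of cells at T1 and T2 in mouse 2416. In the normal-emptying mice they took 7.79% (6.86 to 8.81) and 6.77% (5.83 to 7.81) in mouse 2860, and 7.01% (6.13 to 7.97) and 5.03% (4.37 to 5.76) in mouse 2863. The mean change was -0.386 ± 1.99 points (SD, n = 3; exact permutation p = 0.75), inside the spread between mice. It was -1.5 without either library of mouse 2416, 0.41 without either of mouse 2863 and 0.0511 over leukocytes alone. Non-classical monocyte-like cells changed by 1.31 ± 2.55 points (SD, n = 3) and B cell-like cells by -5.85 ± 13.6 points (SD, n = 3; -21.4 in mouse 2416). Both means changed sign on leaving out 1 library, to -0.161 for non-classical monocyte-like cells without either library of mouse 2860 and to 1.92 for B cell-like cells without either library of mouse 2416. Finer clustering gave 0.048 for the former. Neutrophil-like cells of the delayed library lay for the most part in other clusters than those of the remaining libraries. A cluster led by Retnlg, Lcn2 and S100a8 held 42.5% of them, and 4.0% to 8.37% in the other 5 libraries. A cluster led by the interferon-stimulated genes Slfn4, Rsad2, Oasl2 and Ifit1 held 22%, against 12.2%, 11.6%, 3.52%, 11.6% and 10.4% in the others. The cluster led by Csf3r, Il1b, Mmp9 and Cxcr2 held 22.2%, against 72.1% to 79.0%. These clusters are set apart by the same genes that differ between libraries, so values within the class are given beside them and their sizes are no separate result.

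**Figure D1:**
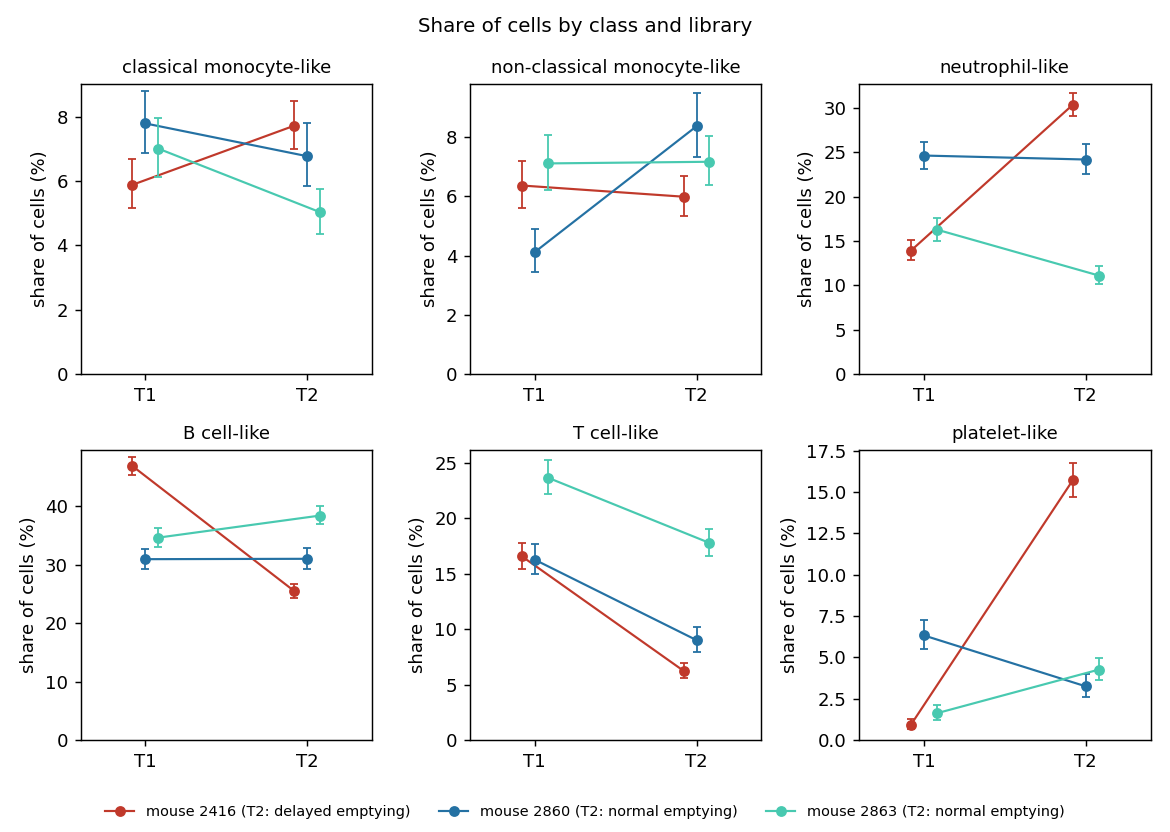
Share of cells (%) in 6 cell classes at T1 and T2, 1 line per mouse, with bars for exact 95% intervals of counting error. The T cell-like share is lower at T2 in each mouse, and the neutrophil-like and platelet-like shares rise steeply in mouse 2416, to 30.4% and 15.7%.

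Ly6c2, Cx3cr1 and Ly6g, genes of proteins named in the series title, were read in classical monocyte-like cells. Ly6c2 (ENSMUSG00000022584, GRCm38 chromosome 15, 75108158 to 75111970), which encodes Ly6C, stood at 944 ± 45.8 CPM in the diabetic libraries (SD, n = 3), 663 ± 83.9 in the normal-emptying libraries (SD, n = 2) and 1238 in the delayed library (n = 1). Cx3cr1 (ENSMUSG00000052336, chromosome 9, 119901616 to 120069879), the fractalkine receptor, stood at 460.1 ± 27.7, 420 ± 7.95 and 479 CPM. Each cell was thinned to 2000 UMIs, with 1, 3, 4, 1, 1 and 1 cells left out for depth in the order of libraries above. Ly6c2 was seen in 67.0% (60.3 to 73.1), 72.8% (68.0 to 77.2), 61.5% (54.9 to 67.8), 57.5% (49.8 to 64.9), 64.2% (57.4 to 70.6) and 51.8% (44.5 to 59.0) of classical monocyte-like cells. Unthinned, the shares were 94.1%, 94.5%, 91.5%, 87.4%, 94.4% and 82.1% at median depths of 14169, 22865.5, 15862, 12252, 16035 and 13792.5 UMIs. B cell-like cells, which should lack Ly6c2, gave 1.2%, 1.49%, 0.541%, 0.526%, 0.751% and 0.415% thinned (16, 52, 8, 40, 2 and 49 cells left out). Unthinned B cell-like cells gave 2.77%, 4.84%, 2.79%, 1.5%, 2.91% and 1.0% at median depths of 6124.5, 8353.5, 6464, 5281, 6714 and 5455.5 UMIs. Ly6c2 is among the markers that name this class, so its share describes the class as named. Ly6g, the gene of the neutrophil protein Ly6G, was seen in 0 thinned classical monocyte-like cells in each library, with upper 95% limits from 0.969% to 2.10%. These limits bound the share of cells with a UMI at that depth, not the share that express the gene. Unthinned it was seen in 0, 3, 0, 2, 0 and 0 of them (0.785% in the delayed library and 1.14% in normal 2860), against 13.2% to 32.2% of neutrophil-like and 0% to 0.125% of B cell-like cells. It was seen in 16.5% of thinned neutrophil-like cells of the delayed library, against 6.75% to 9.86% in the other 5.

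**Figure D2:**
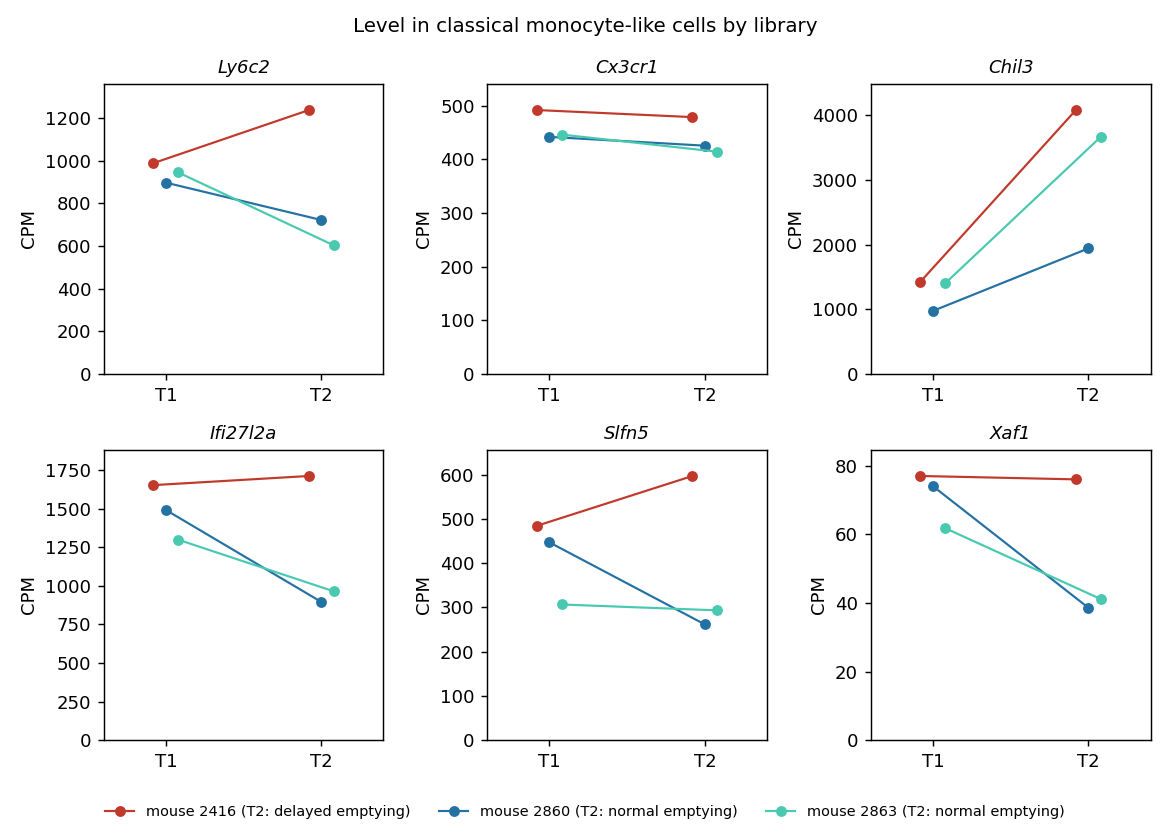
CPM of Ly6c2, Cx3cr1, Chil3 and the interferon-stimulated genes Ifi27l2a, Slfn5 and Xaf1 in classical monocyte-like cells at T1 and T2, 1 line per mouse. Ly6c2 goes from 989 to 1238 CPM in mouse 2416 and down in mice 2860 and 2863, Cx3cr1 differs little between libraries, and Chil3 is at its highest, 4076 CPM, in the delayed library.

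Which genes of classical monocyte-like cells differed between T2 and T1, whatever the gastric emptying? Nuclear-encoded genes of oxidative phosphorylation, which make up the respiratory chain, fell as a group (median log2 change -0.21, 50 of 53 lower, adjusted p = 3.5e-15; adjusted p = 0.485 with an estimated correlation). Ribosomal protein genes fell as well (-0.18, 56 of 58 lower, adjusted p = 2.9e-12; adjusted p = 0.514 with an estimated correlation). No single member of either list passed over all genes. Adjusted over the list alone, 4 oxidative phosphorylation genes and 0 ribosomal genes fell. Ndufa1, a subunit of complex I, stood at -0.40 ± 0.10 (log2, SE, 3 against 3 libraries; adjusted p = 0.355). Rpl39, a protein of the large ribosomal subunit, stood at -0.42 ± 0.11 (adjusted p = 0.364). Classical monocyte identity genes rose as a group (0.11, 12 of 18 higher, adjusted p = 0.0018; adjusted p = 0.514 with an estimated correlation), 6 of them adjusted over the list alone and 0 over all genes. Among them were Vcan, a matrix proteoglycan, at 1.45 ± 0.24 (adjusted p = 0.0955) and Chil3, a chitinase-like secreted protein, at 1.35 ± 0.24 (adjusted p = 0.11). The C-type lectins Clec4e and Clec4d stood at 1.11 ± 0.16 and 0.99 ± 0.15 (adjusted p = 0.0767 for each). Of the 2 clusters in the class, 1 was found almost wholly at T2. It is led by Chil3, Plcb1 and Arhgef37, with Vcan and Fn1 among its 10 leading genes, and has a median of 4098.5 UMIs. It held 0, 3 and 0 cells at T1 and 38, 22 and 17 at T2 in mice 2416, 2860 and 2863, which is 0%, 1.28% and 0% of the class against 9.95%, 12.6% and 8.67%. The values of Vcan and Chil3 above do not by themselves separate a change within cells from a change in the make-up of the class. Finer clustering, in which both classical monocyte-like clusters hold cells of all 6 libraries, gave 1.57 for Vcan (adjusted p = 0.0216) and 1.36 for Chil3 (adjusted p = 0.0486).

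Neutrophil-like monocyte genes also rose as a group (median 0.18, adjusted p = 0.0255; adjusted p = 0.485 with an estimated correlation). Their mean level changed by 0.77, -0.50 and 0.87 in mice 2416, 2860 and 2863, and that of neutrophil transcripts in the same cells by 1.24, -1.46 and 0.92. So did non-classical monocyte identity genes such as Eno3 and Adgre4 (0.15, 16 of 21 higher, adjusted p = 0.0283; adjusted p = 0.519 with an estimated correlation), with mean changes of 0.29, -0.07 and 0.23. Circadian clock genes such as Cry1 and Tef rose too (0.26, 7 of 10 higher, adjusted p = 0.0428; adjusted p = 0.485 with an estimated correlation). Members of these lists that passed numbered 0 over all genes, and 3, 0 and 0 adjusted over the list alone. Interferon-stimulated genes fell as a group (-0.20, 37 of 45 lower, adjusted p = 1.1e-04; adjusted p = 0.755 with an estimated correlation; 0 over all genes and 0 adjusted over the list alone). Their mean level changed by 0.21, -0.95 and 0.04 in mice 2416, 2860 and 2863. Antioxidant and NRF2 target genes fell as a group too (-0.13, 20 of 22 lower, adjusted p = 0.0106; adjusted p = 0.485 with an estimated correlation; 0 over all genes and 0 adjusted over the list alone). Red cell transcripts were higher (median 3.87, 7 of 7, adjusted p = 1.1e-08; adjusted p = 0.485 with an estimated correlation), 5 of them adjusted over the list alone. Platelet transcripts were lower (-0.98, 6 of 6, adjusted p = 3.3e-04; adjusted p = 0.485 with an estimated correlation), 4 of them adjusted over the list alone, with mean changes of 0.28, -2.31 and -1.0. Ly6c2 (-0.14 ± 0.21, adjusted p = 0.874) and Cx3cr1 (-0.06 ± 0.10, adjusted p = 0.877) did not pass.

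With edgeR, 0 of 10653 genes passed for T2 against T1 (996 at an unadjusted p under 0.05; DESeq2 called 39, with 9088 genes left without an adjusted p). Clec4e and Clec4d were among the genes with the smallest adjusted p, 0.0767. With mouse as a block, 7 genes passed, among them Vcan (1.51, adjusted p = 0.0171), Clec4e (1.12, adjusted p = 0.0385) and Chil3 (1.30, adjusted p = 0.0056). Without a low-count filter 23 passed. Finer clustering gave 9 and ended the calls of the interferon-stimulated, non-classical, antioxidant and circadian lists (adjusted p = 0.0642, 0.268, 0.203 and 0.134). The antioxidant call also ended with the stricter cell filter (adjusted p = 0.149) and the circadian call with doublets kept (adjusted p = 0.062). Leaving out the delayed library gave 34 genes and 6 called lists in place of 10. Leaving out diabetic 2416, normal 2863 or normal 2860 gave 7, 6 and 1 genes. The interferon call ended without normal 2860 (adjusted p = 0.997) or diabetic 2860 (adjusted p = 0.054), and that of classical identity without the delayed library (adjusted p = 0.355). The neutrophil-like call ended without the delayed library, diabetic 2416 or diabetic 2863 (adjusted p = 0.355, 0.0575 and 0.293). The antioxidant call ended without diabetic 2416 or normal 2860 (adjusted p = 0.0575 and 0.0595). The non-classical and circadian calls ended without diabetic 2416 (adjusted p = 0.182 and 0.0575), the delayed library (0.126 and 0.186), diabetic 2860 (0.0632 and 0.12) or normal 2863 (0.415 and 0.0582).

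What distinguished classical monocyte-like cells of mice with normal emptying from the diabetic libraries? All diabetic libraries are T1, and the normal-emptying and delayed libraries are T2. In each class, comparing either with the diabetic libraries does not separate gastric emptying from T2 against T1. A batch that follows T1 and T2 cannot be told apart either. Interferon-stimulated genes were lower. Ifi27l2a (ENSMUSG00000079017, chromosome 12, 103442167 to 103443680) stood at 929.9 ± 48.7 CPM (SD, n = 2) against 1481 ± 177 (SD, n = 3) and fell by 0.67 ± 0.11 (log2, SE; adjusted p = 0.0332). Xaf1, a pro-apoptotic interferon target (ENSMUSG00000040483, chromosome 11, 72301629 to 72313733), fell by 0.83 ± 0.15 (adjusted p = 0.0413). As a group they fell (median -0.46, 44 of 45 lower, adjusted p = 6.2e-18; adjusted p = 0.673 with an estimated correlation), 2 over all genes and 14 adjusted over the list alone. Within mice the mean level of the list changed by -0.95 in mouse 2860 and by 0.04 in mouse 2863, so it fell in 1 of the 2 normal-emptying mice. Among the genes that rose was Vcan (ENSMUSG00000021614, chromosome 13, 89655312 to 89742509; 1.33 ± 0.24, from 74.2 ± 31.7 to 186 ± 8.21 CPM). Pla2g7, a secreted phospholipase, and Hdac8, a histone deacetylase, rose as well (0.68 ± 0.12 each). The remaining genes that fell by the same rule were Rps27rt, a copy of a ribosomal gene (-1.1), AI839979 (-1.02) and the ribonucleases Rnaset2a (-0.97) and Rnase6 (-0.73). With them fell Ost4, a subunit of the oligosaccharyltransferase (-0.81), Hmgb2, a chromatin protein (-0.67), Tomm7, of the mitochondrial import complex (-0.65), and Snrpf, of the spliceosome (-0.64).

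Oxidative phosphorylation genes fell as a group (-0.14, 47 of 53 lower, adjusted p = 4.3e-08; adjusted p = 0.685 with an estimated correlation), 0 over all genes and 4 adjusted over the list alone. Ribosomal protein genes did too (-0.10, 53 of 58 lower, adjusted p = 2.6e-05; adjusted p = 0.685 with an estimated correlation), 0 over all genes and 5 adjusted over the list alone. Antioxidant and NRF2 targets also fell as a group (-0.17, adjusted p = 0.0404; adjusted p = 0.673 with an estimated correlation; 0 over all genes and 0 adjusted over the list alone), a call that ended with mouse as a block (adjusted p = 0.082), doublets kept (0.06), the stricter cell filter (0.369) and finer clustering (0.333). Platelet transcripts were lower (-1.16, adjusted p = 0.0013; adjusted p = 0.673 with an estimated correlation). Red cell transcripts were higher (4.51, adjusted p = 3.4e-09; adjusted p = 0.673 with an estimated correlation), with Hba-a1 at 4.86 ± 0.48 and Hbb-bs at 5.06 ± 0.57 (adjusted p = 0.00308 for each). Ly6c2 stood at -0.51 ± 0.10 (adjusted p = 0.0678) and Cx3cr1 at -0.13 ± 0.09 (adjusted p = 0.607).

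In this comparison 34 genes passed, 19 higher and 15 lower (2 against 3 libraries, edgeR), and 38 with mouse as a block, 17 of them called both ways. With the block Xaf1 (-0.76, adjusted p = 0.12), Ifi27l2a (-0.58, adjusted p = 0.0708) and Hdac8 (0.66, adjusted p = 0.129) did not pass. DESeq2 called 89, with 4544 genes left without an adjusted p, no low-count filter gave 59 and the stricter cell filter 19. The larger side changed with DESeq2 (29 higher, 60 lower), with no low-count filter (28 and 31) and without diabetic 2416 (19 and 34). Stricter cells or finer clustering ended the call of the ribosomal list (adjusted p = 0.61 and 0.602). Leaving out normal 2863 gave 10 genes, diabetic 2863 12, diabetic 2416 53 and normal 2860 67 (and 10 lists in place of 6). The antioxidant call ended without diabetic 2416, normal 2860 or diabetic 2863 (adjusted p = 0.114, 0.343 and 0.0824).

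What distinguished the delayed-emptying library from the diabetic ones? Here too, gastric emptying is not separated from T2 against T1. Classical monocyte identity genes rose as a group (median 0.38, 16 of 18 higher, adjusted p = 2.8e-11; adjusted p = 0.348 with an estimated correlation), 3 of them over all genes and 9 adjusted over the list alone, with 1 that fell. Chil3 (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564) rose by 1.68 ± 0.26 (log2, SE; adjusted p = 0.0181), from 1268 ± 254 (SD, n = 3) to 4076 CPM (n = 1). Vcan rose by 1.65 ± 0.27 (adjusted p = 0.0247) and Clec4d by 1.04 ± 0.18 (adjusted p = 0.0249). Neutrophil-like monocyte genes rose (0.41, adjusted p = 1.3e-05; adjusted p = 0.195 with an estimated correlation). Of these, Chil3 and Lcn2, an iron-binding lipocalin of granules (2.05 ± 0.38, adjusted p = 0.0454, from 8.98 ± 4.94 to 37.7 CPM), passed over all genes and 6 adjusted over the list alone. Transcripts of neutrophils were higher in the same cells (0.95, adjusted p = 0.0068; adjusted p = 0.483 with an estimated correlation).

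Ribosomal protein genes fell as a group (-0.33, 56 of 58 lower, adjusted p = 1.7e-40; adjusted p = 0.382 with an estimated correlation; 0 over all genes and 41 adjusted over the list alone). Those of oxidative phosphorylation fell (-0.29, 51 of 53 lower, adjusted p = 4.9e-23; adjusted p = 0.411 with an estimated correlation; 0 and 0). So did the mitochondrially encoded transcripts (-0.49, 12 of 13 lower, adjusted p = 1.2e-11; adjusted p = 0.181 with an estimated correlation; 0 over all genes, and 8 lower and 1 higher, mt-Nd6, adjusted over the list alone). Interferon-stimulated genes rose as a group (0.26, 39 of 45 higher, adjusted p = 1.7e-08; adjusted p = 0.483 with an estimated correlation), 0 over all genes and 1 adjusted over the list alone. Oas2, an activator of RNA decay, stood at 1.29 ± 0.26 (adjusted p = 0.0648). Smaller calls were heat shock genes (-0.18, adjusted p = 0.0295), antioxidant and NRF2 targets (-0.11, adjusted p = 0.0416) and circadian clock genes (0.14, adjusted p = 0.0485), with adjusted p = 0.483, 0.483 and 0.411 with an estimated correlation. In these lists 0 members passed over all genes, and 1 heat shock gene fell, 0 antioxidant genes passed and 3 circadian genes rose adjusted over the list alone. Red cell transcripts were higher (2.61, adjusted p = 2.1e-05; adjusted p = 0.447 with an estimated correlation). Platelet transcripts were lower (-0.76, adjusted p = 0.0212; adjusted p = 0.483 with an estimated correlation). Lysmd4, a LysM-domain protein (ENSMUSG00000043831, chromosome 7, 67222544 to 67307330), rose by 1.57 ± 0.13 (adjusted p = 6.2e-04). Lars2, the mitochondrial leucyl-tRNA synthetase (ENSMUSG00000035202, chromosome 9, 123366927 to 123462666), fell by 1.26 ± 0.18 (adjusted p = 0.011), from 864 ± 78.1 to 362 CPM. Ly6c2 (0.39 ± 0.12, adjusted p = 0.286) and Cx3cr1 (0.06 ± 0.12, adjusted p = 0.932) did not pass.

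In all, 38 genes passed, 34 higher and 4 lower (1 against 3 libraries, the spread of the delayed group assumed equal to that of the others). With mouse as a block, which compares the delayed and the diabetic library of mouse 2416, 9 passed, 2 higher and 7 lower, 4 of them called both ways. Chil3 (1.52) and Lars2 (-1.28) stayed at an adjusted p of 0.0401 each. Vcan (1.11, adjusted p = 0.356), Clec4d (adjusted p = 0.413), Lcn2 (2.17, adjusted p = 0.621) and Lysmd4 (1.51, adjusted p = 0.0564) did not pass. The calls of circadian and platelet transcripts ended, the latter with a median of 0.12. The excess of higher genes thus turned round with the block. DESeq2 called 76, 11 higher and 65 lower, but left 10120 of the 10653 genes without an adjusted p, so its balance covers other genes than that of edgeR. No low-count filter gave 71, finer clustering 69 and the stricter cell filter 24. No low-count filter ended the calls of the neutrophil-like monocyte (adjusted p = 0.433), interferon (0.12), heat shock and platelet (0.071 each), circadian and red cell (0.348 each) and neutrophil transcript lists (0.762). Finer clustering ended those of heat shock (adjusted p = 0.561) and of the antioxidant, circadian and neutrophil transcript lists (0.252 each). Doublets kept ended those of the antioxidant (adjusted p = 0.104), circadian (0.082) and red cell lists (0.439), the stricter cell filter the antioxidant call (0.0986) and the size factors of DESeq2 the circadian call (0.0527). Leaving out diabetic 2863 gave 10 genes and normal 2863 65. Without diabetic 2416 the heat shock (adjusted p = 0.142) and antioxidant calls (0.102) ended, and without diabetic 2863 the heat shock (0.301), antioxidant (0.117) and neutrophil transcript calls (0.148). The platelet call ended without diabetic 2860 (adjusted p = 0.44). The circadian call ended without diabetic 2416, diabetic 2860, normal 2860 or normal 2863 (adjusted p = 0.0598, 0.133, 0.057 and 0.0581).

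How did classical monocyte-like cells differ between delayed and normal emptying? Interferon-stimulated genes were higher in 45 of 45 (median 0.75, adjusted p = 1.1e-32; adjusted p = 0.421 with an estimated correlation), 7 rose over all genes and 30 adjusted over the list alone. Slfn5, a Schlafen family protein (ENSMUSG00000054404, chromosome 11, 82951349 to 82964840), rose by 1.1 ± 0.20 (log2, SE; adjusted p = 0.0403), from 277.5 ± 22.5 (SD, n = 2) to 597 CPM (n = 1). Its relative Slfn1 rose by 1.05 ± 0.18, Xaf1 by 0.93 ± 0.17, Ifi27l2a by 0.88 ± 0.14 (adjusted p = 0.0204) and Phf11b by 0.87 ± 0.17. Ifi209, a DNA-binding p200 family member, rose by 0.86 ± 0.14 (adjusted p = 0.0192), from 165 ± 3.25 to 300.2 CPM. Ly6c2 rose by 0.90 ± 0.13 (adjusted p = 0.0102) and was the member of the classical identity list that passed over all genes (median 0.31, 15 of 18 higher, adjusted p = 1.4e-05; adjusted p = 0.421 with an estimated correlation; 3 adjusted over the list alone). Cx3cr1 stood at 0.19 ± 0.12 (adjusted p = 0.639). Further genes that rose were Lysmd4 (1.86 ± 0.16, adjusted p = 5.7e-04), Rps27rt (1.14) and Rnaset2a (1.0).

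Genes that fell in the delayed library were Il31ra, a cytokine receptor (-1.95 ± 0.34), Lars2 (-1.78 ± 0.19, adjusted p = 0.00148), Cmss1, a nucleolar protein (-1.66 ± 0.28), and Gphn, the scaffold gephyrin (-1.52 ± 0.20). Agpat4, of phospholipid synthesis (-0.87), Tbc1d8 (-0.78), Plin2, a lipid droplet coat protein (-0.76), also fell, as did mt-Co2 (-0.70) and mt-Atp6 (-0.69), of complex IV and the ATP synthase. Il31ra and Lars2 were lower in the other classes tested as well, as given below. Gm42418 (ENSMUSG00000098178), chosen after its values were seen, went the same way (-2.15 ± 0.21, adjusted p = 0.00102), with 20207 CPM in the delayed library and 55293 to 93653 in the others. Mitochondrially encoded transcripts fell as a group (-0.53, 12 of 13 lower, adjusted p = 3.8e-10; adjusted p = 0.223 with an estimated correlation; 2 over all genes, and 9 lower and 1 higher adjusted over the list alone). Lower as groups were also ribosomal protein genes (-0.25, 48 of 58 lower, adjusted p = 2.2e-14; adjusted p = 0.583 with an estimated correlation; 0 and 8) and oxidative phosphorylation genes (-0.09, adjusted p = 0.00203; adjusted p = 0.786 with an estimated correlation; 0 and 0). NF-kB and inflammatory genes fell (-0.11, adjusted p = 0.0283; adjusted p = 0.421 with an estimated correlation), of which Bcl2a1b, an anti-apoptotic BCL2 relative, fell over all genes (-2.17 ± 0.29, adjusted p = 0.00639) and 5 adjusted over the list alone.

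Neutrophil-like monocyte genes rose as a group (0.51, 15 of 20 higher, adjusted p = 0.00707; adjusted p = 0.421 with an estimated correlation). Within mice their mean level rose by 0.77 in mouse 2416 and by 0.87 in the normal-emptying mouse 2863, and fell by 0.50 in mouse 2860. So did migration and adhesion receptors such as Itgam and Itgb2 (0.18, 14 of 18 higher, adjusted p = 0.0118; adjusted p = 0.421 with an estimated correlation). MHC class I genes such as B2m rose too (0.14, 11 of 16 higher, adjusted p = 0.0182; adjusted p = 0.718 with an estimated correlation). In these 3 lists 0 members rose over all genes and 2, 1 and 1 adjusted over the list alone, where 1 neutrophil-like gene fell. Transcripts of neutrophils were higher (0.98, 8 of 8, adjusted p = 0.0283; adjusted p = 0.718 with an estimated correlation). Those of red cells were lower (-1.90, 7 of 7, adjusted p = 5.6e-04; adjusted p = 0.583 with an estimated correlation). Non-classical identity genes did not pass (adjusted p = 0.795), with a median of 0.03 and a test that pointed down.

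Between delayed and normal emptying 77 genes passed, 58 higher and 19 lower (1 against 2 libraries). With mouse as a block 19 passed, 6 higher and 13 lower, 5 of them called both ways. Lars2 (-1.81) and Gphn (-1.72), each at an adjusted p of 0.00737, and Cmss1 (-2.27, adjusted p = 0.00366) passed. Ly6c2 (0.80, adjusted p = 0.265), Slfn5 (0.72, adjusted p = 0.585), Ifi27l2a (0.63, adjusted p = 0.442), Xaf1 (0.74, adjusted p = 0.551) and Lysmd4 (1.78, adjusted p = 0.0545) did not. At the preset correlation the interferon list kept its call with the block (adjusted p = 4.1e-13), and those of oxidative phosphorylation (adjusted p = 0.944) and migration (adjusted p = 0.0897) did not. An estimated correlation, at which no list was called without the block, was not run with it. The block sets the change of the interferon list in mouse 2416, 0.21, against -0.95 and 0.04 in mice 2860 and 2863. The stricter cell filter gave 41 genes. No low-count filter ended the calls of the neutrophil-like monocyte (adjusted p = 0.996), classical identity (0.146), migration (0.465), MHC class I (0.51) and neutrophil transcript lists (0.769). Finer clustering ended those of NF-kB (adjusted p = 0.819) and red cell transcripts (0.94), and doublets kept that of NF-kB (0.0664). Leaving out normal 2863 gave 27 genes, 6 lists in place of 11 and no call of Ly6c2. Leaving out diabetic 2863 gave 38 genes and normal 2860 49, of which 19 were higher and 30 lower. Without normal 2863 the calls of NF-kB (adjusted p = 0.0944), oxidative phosphorylation (0.137), migration (0.069), neutrophil (0.069) and red cell transcripts (0.0851) ended. Without normal 2860 those of MHC class I (adjusted p = 0.712) and neutrophil transcripts (0.079) ended.

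**Figure D3:**
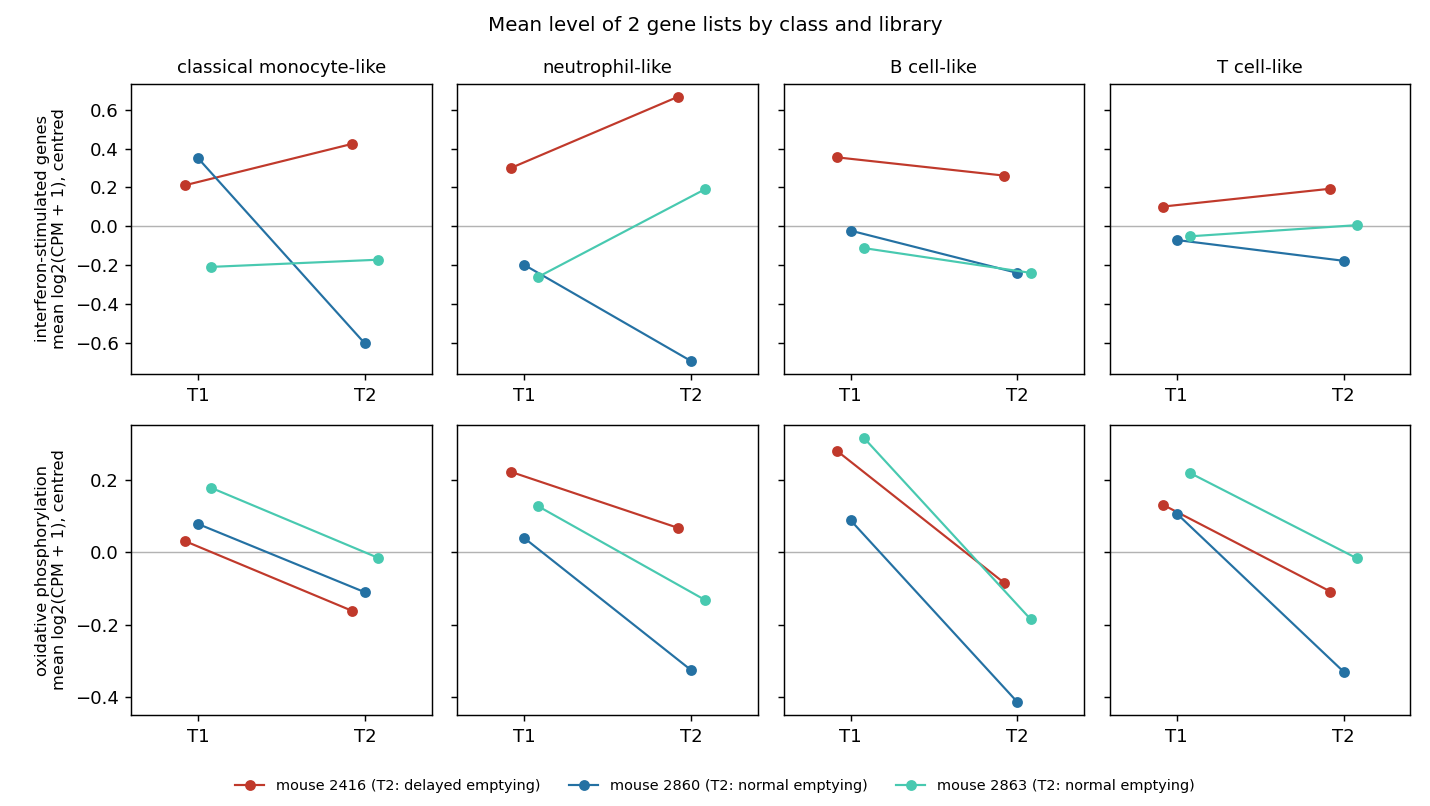
Mean level of the interferon-stimulated list (top) and of the oxidative phosphorylation list (bottom), as mean log2(CPM + 1) centred over the libraries, in 4 classes at T1 and T2, 1 line per mouse. The oxidative phosphorylation list is lower at T2 in each mouse and class, whereas interferon-stimulated genes of classical monocyte-like cells fall in mouse 2860, by a change of -0.95, and not in mouse 2863, with 0.04.

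Did the other abundant classes show these changes? Between T2 and T1, neutrophil-like cells had 1 called gene, Filip1l, a filamin-binding protein chosen after its values were seen (2.35 ± 0.20 on the log2 scale, adjusted p = 1.6e-04; 8.59, 13.5 and 12.5 CPM at T1 and 58.4, 68.3 and 53.2 at T2 in mice 2416, 2860 and 2863). In the delayed library against the diabetic ones 257 genes passed, 215 higher and 42 lower. Ly6c2 rose by 1.72 ± 0.26 (adjusted p = 0.00225), from 49.5 ± 5.33 (SD, n = 3) to 163 CPM. Without TMM factors Ly6c2 stood at 56.5 and 155 CPM in mouse 2416 (T1 and T2). It stood at 49.3 and 56.2 in mouse 2860 and 44.5 and 127 in mouse 2863, so a normal-emptying mouse rose as well. The membrane protein Ifitm1 rose by 1.62 ± 0.26, the interferon-stimulated Ifit3 by 1.51 ± 0.36, Lcn2 by 1.43 ± 0.17 and Oprm1 by 1.4 ± 0.14. Il31ra fell by 1.64 ± 0.34, Lars2 by 1.57 ± 0.20, Gphn by 1.31, Inpp4b by 1.17 and Dynll1 by 1.16. Against normal emptying 262 passed, 192 higher and 70 lower, with Ifi27l2a (1.95 ± 0.37), Ifit3 (1.75 ± 0.42), Rtp4 (1.42) and Isg15 (1.4) higher. Lower were Lars2 (-1.55), Gphn (-1.48), Il31ra (-1.39), March3 (-1.29) and Pde3b (-1.18). Interferon-stimulated genes rose as a group against diabetic (median 0.69, 38 of 40 higher, adjusted p = 7.8e-17; adjusted p = 0.724 with an estimated correlation) and normal emptying (0.83, 38 of 40, adjusted p = 3.5e-17; adjusted p = 0.646 with an estimated correlation). Of them, 8 and 10 rose over all genes and 23 and 26 adjusted over the list alone. Within mice the mean level of the list changed by 0.37 in mouse 2416, -0.50 in mouse 2860 and 0.45 in mouse 2863, so a normal-emptying mouse rose more than the delayed one. In the same cells the mean level of platelet transcripts changed by 1.56, -1.04 and 0.60 in mice 2416, 2860 and 2863, with the signs of the interferon list, and that of red cell transcripts by -0.37, 3.77 and 3.01. The cluster led by Retnlg, Lcn2 and S100a8 took 42.5% of this class in the delayed library and 4.0% to 8.37% in the others. The gene and list values of neutrophil-like cells therefore do not separate a change within cells from a change in the make-up of the class. Normal emptying against diabetic gave 40 genes, 20 each way, with Cep83 (0.92), Itpkb (0.88), Lcn2 (0.75), Bmpr1a (0.74) and Mta3 (0.73) higher. Ost4 (-1.28), Evi2 (-1.15), Ndufb1-ps (-0.94) and Rps27 (-0.93) fell. Most genes called in this class for the delayed library, against diabetic or normal emptying, were not called with mouse as a block. With mouse as a block the 4 counts were 1, 74, 193 and 121. Ifit3 (adjusted p = 0.354), Ifi27l2a (0.87, adjusted p = 0.0614) and Isg15 (adjusted p = 0.344) did not pass between delayed and normal emptying. Leaving out 1 library moved the first count to 52 (delayed; 22 higher, 30 lower), 5 (normal 2860) or 2 (diabetic 2860). The delayed against diabetic count moved to 86 (diabetic 2863) or 136 (diabetic 2860), and the delayed against normal count to 79 (normal 2860), 89 (diabetic 2863), 123 (normal 2863) or 520 (diabetic 2416). For normal emptying against diabetic it moved to 7 (diabetic 2863), 9 (normal 2863) or 76 (diabetic 2416).

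In B cell-like cells oxidative phosphorylation genes fell at T2 (median -0.45, 53 of 53 lower, adjusted p = 5.6e-33; adjusted p = 0.355 with an estimated correlation), 4 over all genes and 48 adjusted over the list alone. For T2 against T1, 47 genes passed, 13 higher and 34 lower. Pard3b (0.90 ± 0.11), Nr3c2, the mineralocorticoid receptor (0.88), Pbx3 (0.83), Atxn1 (0.75) and Ccr6, a chemokine receptor (0.68), rose. Ost4 (-0.85), the light chain constant genes Iglc2 (-0.84) and Iglc1 (-0.75), Tmem258 (-0.72) and Atp5k (-0.72) fell. A cluster led by Agbl1, Iglc1 and Vpreb3, with Iglc2 among its leading genes, took 21.2%, 9.11% and 10.8% of the class at T1 and 3.73%, 6.49% and 4.75% at T2 in mice 2416, 2860 and 2863. A larger cluster led by Gm47782, Bank1 and Cr2 took 25.7%, 33.4% and 28.4% at T1 and 59.2%, 57.7% and 47.7% at T2. The cluster led by Cd79a, Iglc3 and Igkc took 51.8%, 57.0% and 60.0% at T1 and 35.9%, 35.6% and 47.1% at T2. The values of this class, those of oxidative phosphorylation genes included, therefore do not separate a change within cells from a change in its make-up. Normal emptying against diabetic gave 1622 genes, 714 higher and 908 lower, with Cmss1 (0.97), Pard3b (0.94), Pbx3 and Nr3c2 (0.92 each) and Atxn1 (0.84) higher. Ifi27l2a (-1.40 ± 0.19, adjusted p = 0.00128), Rps27rt (-1.19), Ost4 (-1.1) and Agbl1 (-0.99) fell. Of the list, 48 of 53 oxidative phosphorylation genes fell over all genes and 52 adjusted over the list alone. From T1 to T2 the mean level of platelet transcripts in this class changed by 1.28, 0.32 and 1.74 in mice 2416, 2860 and 2863. A normal-emptying mouse thus rose more than the delayed one. That of neutrophil transcripts changed by 1.69, 0.65 and 0.27. The delayed library gave 216 genes against diabetic (175 higher, 41 lower; Ms4a6c 1.03, S100a6 0.83, Agbl1 -2.21, Lars2 -1.34, Hist1h1e -1.31). It gave 334 against normal emptying (249 higher, 85 lower; Tsix 1.67, Rps27rt 1.39, Ifi27l2a 1.07, Il31ra -2.32, Lars2 -1.87, Cmss1 -1.61). Transcripts of neutrophils (median 1.70, adjusted p = 9.0e-11) and platelets (2.05, adjusted p = 3.0e-06) were also higher in B cell-like cells of the delayed library than of the diabetic ones, with adjusted p = 0.292 and 0.298 with an estimated correlation. Between delayed and normal emptying interferon-stimulated genes rose as a group (0.55, 39 of 42 higher, adjusted p = 1.7e-07; adjusted p = 0.556 with an estimated correlation), a call that ended with mouse as a block (adjusted p = 0.546). With the block the 4 counts were 524, 2710, 1210 and 783. The third was 530 higher and 680 lower, so the excess of higher genes against diabetic turned round. Of these 47, 1585, 216 and 259 genes were called both ways. For T2 against T1, leaving out diabetic 2416, diabetic 2863, normal 2863, diabetic 2860, normal 2860 or the delayed library gave 2, 3, 4, 15, 20 and 1638 genes. Higher genes were the larger part without diabetic 2863 (2 higher, 1 lower), normal 2863 (3 and 1) or normal 2860 (11 and 9), or with the stricter cell filter (4 and 3). Normal emptying against diabetic gave 80 without normal 2860, 471 without diabetic 2863 and 634 without normal 2863. Delayed against diabetic gave 135 without diabetic 2863 and 137 without normal 2863. Delayed against normal gave 84 without normal 2863, 93 without normal 2860 and 746 without diabetic 2416.

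T cell-like cells had 139 called genes for T2 against T1, 93 higher and 46 lower. S100a6, a calcium-binding protein, rose by 1.44 ± 0.24 (adjusted p = 0.0188), and the potassium channel gene Kcnq5 by 1.14 ± 0.16. The cytokine receptor chain Il18rap rose by 1.1, Itgb1, the integrin beta-1 chain, by 1.09 ± 0.18 and Id2, a regulator of effector differentiation, by 0.98. Ost4 (-0.70), Rpl35 (-0.69), Rgcc (-0.67), Dapl1 (-0.64) and Tomm7 (-0.60) fell. The clusters in the class took different shares of it. A cluster led by Ccl5, Cxcr6 and Id2 took 12% and 10.5% with normal emptying (mice 2860 and 2863), 3.88% in the delayed library and 2.24% to 2.56% in the diabetic ones. A cluster led by Ikzf2, Rora and Ctla4 took 14.6% and 14.0%, 5.83%, and 2.72% to 8.35%. A cluster led by Cd8b1 and Cd8a, with Dapl1 among its leading genes, fell from 52.4%, 37.1% and 41.1% at T1 to 35.3%, 26.6% and 33.3% at T2 in mice 2416, 2860 and 2863. The values of S100a6, Id2, Itgb1, Il18rap and the other genes of this class therefore do not separate a change within cells from a change in its make-up. Normal emptying against diabetic gave 649 genes (395 higher, 254 lower), among them S100a6 (1.57 ± 0.23), St6galnac3 (1.51), S100a4 (1.38), Kcnq5 (1.33) and Itgb1 (1.28) higher. Rps27rt (-1.1) and Ost4 (-0.92) fell. The delayed library gave 121 genes against diabetic (108 higher, 13 lower; Ctla2a 1.11, Oprm1 0.92, Il31ra -1.95, Lars2 -1.37). Ctla2a also leads the platelet-like clusters, and platelet transcripts were higher in T cell-like cells of the delayed library (median 2.15, adjusted p = 6.4e-09), as were those of neutrophils (1.4, adjusted p = 8.2e-06; adjusted p = 0.27 for each with an estimated correlation). Within mice 2416, 2860 and 2863 the mean level of platelet transcripts in this class changed by 1.96, 0.99 and 1.83, and that of neutrophil transcripts by 1.41, 0.68 and -0.43. It gave 161 against normal emptying (119 higher, 42 lower; Tsix 1.67, Oprm1 1.27, Il31ra -2.32, Lars2 -1.87, Cmss1 -1.84). Oxidative phosphorylation genes fell at T2 (-0.31, 52 of 53 lower, adjusted p = 2.8e-20; adjusted p = 0.359 with an estimated correlation), 1 over all genes and 23 adjusted over the list alone. With mouse as a block the counts were 329, 1362, 350 and 280. For T2 against T1, finer clustering gave 0 genes with edgeR (1824 at an unadjusted p under 0.05; DESeq2 called 292 with the first clustering). Leaving out diabetic 2416 or diabetic 2863 gave 0 as well (1552 and 1337 at an unadjusted p under 0.05). Without normal 2863 it gave 21, without diabetic 2860 41, without normal 2860 82 and without the delayed library 639. For the other comparisons finer clustering gave 254, 15 and 54. Normal emptying against diabetic gave 208 without normal 2860, 233 without diabetic 2863 and 345 without diabetic 2416. Delayed against diabetic gave 66 without diabetic 2863, 70 without diabetic 2416 and 80 without diabetic 2860. Delayed against normal gave 77 without normal 2860, and 52 higher and 63 lower without normal 2863.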

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

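The fit with mouse as a block was planned, whereas the counts of unnamed cells and of barcodes with few genes were chosen after the data were seen. Whether the T2 minus T1 change of mouse 2416, with delayed emptying, differed from the mean change of the normal-emptying mice was tested gene by gene with mouse as a block. The changes differed for 19 genes in classical monocyte-like, 121 in neutrophil-like, 783 in B cell-like and 280 in T cell-like cells (adjusted p under 0.05, 1 residual degree of freedom). In classical monocyte-like cells the difference of the changes was -1.81 on the log2 scale for Lars2, -2.27 for Cmss1, -1.72 for Gphn, -3.84 for Hbb-bs and -3.90 for Hbb-bt. Lars2 was also lower in the delayed library than with normal emptying in the other classes tested. So were Cmss1 in B cell-like and T cell-like cells and Gphn in neutrophil-like cells, and Hbb-bs and Hbb-bt are red cell transcripts. These differences are thus not particular to classical monocyte-like cells. A difference of the delayed library as a whole was not tested.

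Cells outside the named classes, which the comparisons of genes do not use, also differed between libraries. The unnamed cluster led by Saa3, Prg4, Cxcl13 and C1qa held 31 cells of normal 2860 and 70 of normal 2863 and 0 in the other 4 libraries, where 3 counts would be 0.0606% to 0.0995% of cells. An unnamed cluster led by Stfa1, Lcn2 and Chil3 held 19 cells, each from the delayed library. Among barcodes with fewer than 200 detected genes, those with over 50% haemoglobin UMIs numbered 320 and 230 in mouse 2416 (T1 and T2), 129 and 958 in mouse 2860, and 203 and 499 in mouse 2863. No group holds 4 libraries, so outlying libraries were not tested for.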

How the results depend on the processing

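The share of leukocytes alone was chosen after the data were seen; the remaining alternatives were planned, and the cause of a move was not tested. Counts below are genes called, in the order T2 against T1, normal emptying against diabetic, delayed against diabetic, and delayed against normal emptying where 4 are given.

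With mouse as a block, which respects the pairing, classical monocyte-like cells gave 7 genes for T2 against T1, 9 for delayed against diabetic and 19 for delayed against normal emptying. The block gave 74 in neutrophil-like cells for normal emptying against diabetic and 121 for delayed against normal, 524, 2710, 1210 and 783 in B cell-like cells, and 329, 1362, 350 and 280 in T cell-like cells. DESeq2 called 39, 89 and 76 genes in the first 3 comparisons of classical monocyte-like cells, 16, 130 and 118 in those of neutrophil-like cells, 419 and 123 in B cell-like cells (T2 against T1, delayed against diabetic), and 292, 412, 54 and 93 in T cell-like cells. Without a low-count filter the first 3 comparisons of classical monocyte-like cells gave 23, 59 and 71 genes, and T2 against T1 gave 89 in neutrophil-like, 225 in B cell-like and 286 in T cell-like cells; 5 and 6 lists were called for delayed against diabetic and delayed against normal. At resolution 2, classical monocyte-like cells gave 9 genes (T2 against T1) and 69 (delayed against diabetic), and T cell-like cells 0 (edgeR; 1824 at an unadjusted p under 0.05), 254, 15 and 54. The stricter cell filter gave 19, 24 and 41 genes in the last 3 comparisons of classical monocyte-like cells and 7, 868 and 104 in the first 3 of B cell-like cells. With an estimated correlation 0 lists were called by camera in each comparison.

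Leaving out each library in turn gave 0 to 34, 10 to 67, 10 to 65 and 27 to 94 genes in classical monocyte-like cells, 1 to 52, 7 to 76, 86 to 376 and 79 to 520 in neutrophil-like cells, 2 to 1638, 80 to 1721, 135 to 310 and 84 to 746 in B cell-like cells and 0 to 639, 208 to 822, 66 to 138 and 77 to 132 in T cell-like cells. Called lists ranged over 6 to 11, 6 to 10, 10 to 13 and 6 to 14.

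Directions reversed in these cases in classical monocyte-like cells. For T2 against T1, the non-classical identity list had a median of -0.056 and Eno3 a log2 change of -0.066 at resolution 2. Leaving out each library, Ly6c2 ranged from -0.50 to 0.059 (without normal 2863). For delayed against diabetic, the block gave 0.12 for the platelet list, -0.039 for Cx3cr1 and 0.36 for Ppbp, doublets kept gave 0.065 for Cxcr2, -0.17 for Hbb-bs, -0.080 for Hba-a2 and -0.58 for Hbb-bt, and Cxcr2 ranged from -1.05 to 0.73 (without diabetic 2860) on leaving out each library. For delayed against normal emptying, the list of neutrophil transcripts had a median of 0.36 and a test that pointed the other way without a low-count filter, Mmp8 stood at -0.20 with the block, and at resolution 2 the red cell list stood at 0.17 and Hbb-bt at 0.51.

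Of the remaining gene values, 3017 kept their side of the threshold, 143 came to pass it and 382 no longer passed; of the list medians 369 kept theirs and 111 no longer passed. With the size factors of DESeq2 within edgeR, 290 named gene values kept their side and 1 came to pass. The share changes stayed within the spread between mice in the 30 alternatives for T cell-like, classical monocyte-like and neutrophil-like cells, and in 79 for the other classes; the erythroid cell-like change moved to 0.158 points with the stricter cell filter. Within that spread the platelet-like mean fell from 4.79 to 0.348 points with the same filter, and the means of B cell-like, non-classical monocyte-like and platelet-like cells changed sign on leaving out 1 library, to 1.92, -0.161 and -0.222. Leaving out each library in turn gave mean changes of -8.80 to -6.58, -1.50 to 0.41 and -2.81 to 8.0 points for T cell-like, classical monocyte-like and neutrophil-like cells. Thinning to 1000 UMIs moved 12 shares of cells with a UMI beyond the spread and left 12 within it.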

Other observations

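The tests of the baseline of mouse 2416, of a library batch and of doublets were chosen only after the results had been seen, and the macrophage lists after the leading genes of their cluster had been seen but before the lists were measured. The unnamed cluster led by Saa3, Prg4, Cxcl13 and C1qa made up 1.2% (95% interval 0.817 to 1.70) of the cells of normal 2860 and 1.80% (1.4 to 2.26) of normal 2863. Its cells expressed the acute-phase gene Saa3 (8255 CPM), the lubricin gene Prg4 (4073), the chemokine gene Cxcl13 (2936), the complement gene C1qa (2414), the lipoxygenase gene Alox15 (2352) and Adgre1 (1089), which encodes the macrophage antigen F4/80. Gata6 stood at 198 CPM, in 90.1% of its cells, Timd4 at 249.9, Cd5l at 431 and Vsig4 at 383, whereas the monocyte genes Ly6c2 and Ccr2 stood at 11.1 and 9.61 CPM.

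In other classes, the neutrophil-like monocyte list rose in neutrophil-like cells of the delayed library against the diabetic ones (median 0.57, adjusted p = 9.4e-10; adjusted p = 0.343 with an estimated correlation), 10 of its 24 genes over all genes, among them Ly6g, Lcn2, S100a9 and Wfdc21. Within mouse 2416 the mean level of the list fell by 0.24 (0.35 at T1, 0.11 at T2), while its median change with mouse as a block was 0.35. The other diabetic libraries stood at -0.52 and -0.54, so the rise of the mean is against those libraries. Normal 2863 had the highest mean level, 0.98. The make-up of neutrophil-like cells differed between libraries, so these values do not separate a change within cells from it. Within the normal-emptying mice 2860 and 2863 the list changed by 0.14 and 1.52. Against normal emptying its median was 0.29, its mean -0.23 and its test pointed up (adjusted p = 3.4e-04; adjusted p = 0.636 with an estimated correlation). Oxidative phosphorylation genes were lower in neutrophil-like cells of normal emptying than of diabetic libraries (-0.36, adjusted p = 5.9e-18; adjusted p = 0.491 with an estimated correlation; 3 fell over all genes and 19 adjusted over the list alone) and higher in delayed than in normal emptying (0.30, adjusted p = 4.4e-07; adjusted p = 0.646 with an estimated correlation). Red cell transcripts in these cells rose from T1 to T2 by 3.77 and 3.01 in the normal-emptying mice 2860 and 2863 and changed by -0.37 in mouse 2416. Ribosomal protein genes fell at T2 in neutrophil-like (-0.18), B cell-like (-0.27) and T cell-like cells (-0.36), with adjusted p = 1.2e-07, 3.3e-10 and 4.3e-19, and adjusted p = 0.576, 0.523 and 0.377 with an estimated correlation.

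Interferon-stimulated genes and Ly6c2 were higher in classical monocyte-like cells of the delayed library than of normal emptying. Free RNA from neutrophils, estimated from neutrophil transcripts in B cell-like cells, could account for 0.365% of the difference of the interferon list and 0.055% of that of Ly6c2. In the delayed library, without TMM factors, neutrophil-like cells held less of both than classical monocyte-like cells. The list stood at 6230.7 against 9131.5 CPM and Ly6c2 at 154.92 against 1351.7. Such RNA could thus not have raised monocyte-like cells to these levels in any amount, so the percentages add no separate support. A shift of the class toward non-classical cells is argued against by finer clustering, in which 81.0% of the Ly6c2 difference stayed. A level of mouse 2416 that differed already at T1 cannot be told apart from delayed emptying: in the diabetic libraries its mean level was 0.21 on the log2 scale, between 0.35 in mouse 2860 and -0.21 in mouse 2863. It lay 0.14 above the mean of those mice, 17.2% of the delayed minus normal difference of 0.81 and less than the distance between them, and 1 delayed library leaves it open. That interferon-stimulated genes are higher with delayed emptying is thus a hypothesis, with gastric emptying and the mouse itself both untested as causes. The normal-emptying mice moved apart in that list, by -0.95 in mouse 2860 and 0.04 in mouse 2863 from T1 to T2.

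Oxidative phosphorylation and ribosomal protein transcripts were lower at T2 in 4 classes. The lists lay under the 5th percentile of 10000 lists matched for length and expression. This held in 4 of 4 classes for oxidative phosphorylation and 4 of 4 for ribosomal proteins. The length counts all annotated exons of a gene and need not be that of its transcript. The matched lists were chosen on length and expression alone, whereas genes of 1 list may move together. Whether transcript length is the whole cause is therefore not decided. The matched lists fell as well, to medians of -0.14, -0.05, -0.25 and -0.20 in monocyte-like, neutrophil-like, B cell-like and T cell-like cells for oxidative phosphorylation and -0.13, -0.01, -0.22 and -0.20 for ribosomal proteins, so genes of like length and expression share part of the fall, with the part of each not separated, and in B cell-like cells the ribosomal list stood at a percentile of 4.93. A library batch that follows T1 and T2 cannot be told apart from a change between T1 and T2: the oxidative phosphorylation list was lower in 12 of 12 combinations of mouse and class, and the labels give no batch. Other lists moved with them. Mitochondrially encoded transcripts were lower at T2 in 9 of 9 combinations of mouse and class in neutrophil-like (-0.44, -0.22 and -0.19 in mice 2416, 2860 and 2863), B cell-like (-0.50, -0.12 and -0.20) and T cell-like cells (-0.62, -0.23 and -0.30), and changed by -0.42, 0.016 and 0.073 in classical monocyte-like cells. Immediate-early and dissociation response genes were lower in 9 of 9 as well (-0.0074, -0.50 and -0.053 in neutrophil-like, -0.15, -0.51 and -0.27 in B cell-like, -0.24, -0.21 and -0.21 in T cell-like cells), against 0.11, -0.22 and -0.054 in classical monocyte-like cells. Some clusters with few UMIs grew at T2 in each mouse. A neutrophil-like one (median 1224 UMIs) took 0.928%, 0.962% and 0.746% of cells at T1 and 4.02%, 4.37% and 1.33% at T2 in mice 2416, 2860 and 2863. At resolution 2 a B cell-like one (2818.5 UMIs) held 45, 17 and 8 cells, and then 259, 165 and 152. An unnamed one led by haemoglobin genes (1720.5 UMIs) went from 66 to 50 cells in mouse 2416. A difference in handling, in RNA quality or in the make-up of the classes between T1 and T2 stays open and was not tested. No biological explanation was tested.

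Cells of the cluster led by Saa3 and Prg4 were found in the normal-emptying libraries and not in the others. Doublets are argued against, since 2.89% of these cells were called doublets. A candidate source is macrophages of the peritoneal cavity, whose marker list stood at a median of 4.79 on the log2 scale over the monocyte-like cells, classical and non-classical, of the same libraries (11 of 12 genes over 2-fold), with lists for liver, lung alveolar and brain macrophages at 0 and for splenic red pulp at -0.31. Over 2-fold were also 1 of 7 liver genes, Cd5l (6.42), and 2 of 7 lung alveolar genes, Marco (4.69) and Fabp4 (2.14). Those monocyte-like cells express 4 of the 12 genes at over 10 CPM (Icam2 12.6, F5 32.6, Cd93 44.8 and Laptm5 952), 2 of which, F5 and Cd93, the classical identity list also holds, and the CD45 sort would not remove such cells, in which Ptprc stood at 308 CPM. How they came into the blood samples, through collection or from circulation, was not tested.

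For T2 against T1, the 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. In classical monocyte-like cells the real split called 0 genes (edgeR; 996 at an unadjusted p under 0.05, DESeq2 39) and the highest other 4, so 10 of 10 gave as many. In neutrophil-like cells the counts were 1 and 0, in B cell-like cells 47 and 0, and in T cell-like cells 139 and 1, and 1 of 10 splits gave as many in each. Of the splits that part all 3 pairs of libraries from 1 mouse, the other 3 called 0, 0 and 4 genes in classical monocyte-like cells and 0 in each of the other classes; the split with 4 sets diabetic 2416 beside the normal-emptying libraries.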
